A study of Mus musculus with 12 samples.

How the data were processed

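Gene expression was measured by sequencing of poly(A) RNA in 12 libraries of mouse CD8+ T cells: naive cells at 0 h, and cells activated with antibodies to CD3 and CD28 and cultured at 37 °C for 24 h, at 39 °C for 24 h or at 37 °C for 48 h, with 3 libraries per group. Per the labels' extract protocol, RNA was taken with a column kit with DNase treatment, libraries were made with a stranded mRNA kit and sequenced on an Illumina HiSeq instrument. The deposited values are raw counts of reads per gene, 1 library per file, not pooled or normalised by the authors. For the steps before them, the submitters' processing notes name the mm10 build and STAR, featureCounts, deepTools and DESeq2, without versions or roles. The annotation release, the strand setting and the handling of reads that map to several places are not given in the sources used here. That the values are counts was checked on the files, which hold whole numbers with a different total each.

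Each file lists the same 43629 Ensembl gene IDs in the same order. GENCODE release M21 for GRCm38, the assembly of mm10, gave symbol, biotype and span for 42548 of them. The other 1081 held at most 0.245% of the counts of a library and stayed in the library totals and tests. No count was found in any library for 18989 IDs. The totals ran from 6580649 to 32668776 counts, and the report gives each. The biological coefficient of variation over all genes was 0.145, so at these depths the spread between replicates of well-counted genes came mostly from differences between libraries and not from counting.

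Groups were taken from the labels. The main test was edgeR's quasi-likelihood F test (edgeR 4.0.16, R 4.3.3) on the raw counts, in 1 model of 4 group means over all 12 libraries, with TMM normalisation and without robust estimation. Genes were kept by filterByExpr with its defaults (minimum count 10, minimum total 15), which left 14098. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, with no fold threshold. SE of a log2 fold change was its size divided by the square root of F. Levels are TMM-normalised CPM, except for the sums of markers of other cells, which are CPM of the library totals. A group with no count was set at a floor of 3 counts over the group, and a group of 1 to 3 counts has an exact counting interval, which covers counting error only.

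The comparisons were 39 °C against 37 °C at 24 h, 24 h at 37 °C against naive, 48 h against 24 h at 37 °C, and 48 h at 37 °C against naive (counts of genes only). The tests, the alternatives of the next paragraphs unless said otherwise, the gene lists and the rule for named genes were fixed before the data were examined. The 29 lists, 24 of cell functions and 5 of other cell types, were written from general knowledge of gene function. Each was tested against the other genes with camera at a preset correlation between genes of 0.01, adjusted over the lists, and members were counted by the calls over all genes and by calls adjusted over the list alone. The estimated correlation within a list, used as an alternative, rests on the 12 libraries. The lists overlap in places. Btg2 is in the naive and p53 lists, Pdk1 in the glycolysis and hypoxia lists and Slc7a11 in the ATF4 and NRF2 lists. Rps27l is in the cytosolic ribosomal list only, which takes it by its name. Every member of the other-cell lists was counted in each group, and some of these genes can also be expressed by T cells. The relation of the temperature effect to the effect of the second day was taken as the covariance and correlation of log2 fold changes across genes. It was set beside 50 simulations of negative binomial counts with no effect and 1000 redraws of replicate deviations with the same shared libraries. The count of genes called in 1 direction against both 37 °C groups was set beside 50 redraws of the deviations of whole libraries, with 39 °C means held between those of the 37 °C groups. It was also set beside 50 simulations of negative binomial counts with the same held means.

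The rule for named genes had 4 parts. The first took, for the first 3 comparisons, the 5 largest increases and decreases among called genes with a mean of at least 5 CPM in the higher group and no overlap of replicates, without predicted models. Next came, from each list except those of other cells, the member with the smallest p, or 2 members where the list passed. For 39 °C against 37 °C it also took, whatever their values, Hspa1a, Hspa1b, Hsph1, Dnajb1, Cirbp, Rbm3, Tufm, Ifng, Gzmb, Tnf, Il2, Prf1 and mt-Co1. For the other comparisons it took Ifng, Gzmb, Il2ra, Tcf7, Myc and Mki67, and some genes that the rule took are not reported here. Members of other-cell lists were named for their level. Where at most 5 members of a list went a certain way, members were also named after their values were seen.

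The analysis was repeated with RLE size factors, library size only, no count filter, the compared groups alone, DESeq2 (1.42.0), limma-voom (limma 3.58.1), the replicate number as a block, with an estimated correlation in camera, and each library left out in turn. Added after the data were seen were removal of smooth trends of log2 CPM over gene length and GC content (splines with 4 degrees of freedom per library), alone, with the block and with an estimated correlation. Also added were leaving out naive replicate 1, 37 °C 24 h replicate 3 and 39 °C 24 h replicate 1, which hold the most counts on short genes in their groups, and thinning every library to the lowest total. The labels number replicates alike in all groups and do not say whether a number marks an animal or a day. Correlations of deviations from the group mean over 9248 genes were used to check this. For 48 h against naive, each pair of the same number correlated (0.317, 0.334 and 0.179). For each other comparison, at least 1 pair correlated negatively, and no pairing was assumed. In each negative pair the deviations of the libraries followed gene length in opposite directions. These correlations therefore do not exclude a pairing, and the block was kept as an alternative.

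The procedure was tested on simulated data with known changes. In simulated counts shaped like 39 °C against 37 °C, 31.3% of 1.5-fold, 68.7% of 2-fold and 90.8% of 4-fold changes were found, with 4.55% false calls. For 24 h against naive the shares were 29.2%, 64.6% and 92.4%, with 7.58% false calls. For 48 h against 24 h they were 28.4%, 59.7% and 92.4%. A shifted gene set was found in each and 0 of 20 unshifted sets was called. Genes were drawn independently in these counts, so this could not show false list calls from members that vary together. Figures and tables were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9. Reads were not realigned, since raw reads were not available here, and isoforms, protein levels and mitochondrial translation itself were not analysed here.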

Results

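Polyadenylated RNA was sequenced from mouse CD8+ T cells, the lymphocytes that kill infected and tumour cells, in 12 libraries from 4 groups of 3. Naive cells were isolated by negative selection from spleen and lymph nodes of wild-type C57BL/6 mice and sampled at 0 h. The other groups were activated through CD3 and CD28 with IL-2 in the medium and cultured at 37 °C for 24 h, at 39 °C (a fever-range temperature) for 24 h, or at 37 °C for 48 h. The design text of the series calls the 3 samples of a group independent biological replicates. Counts per gene were deposited. The library totals were 6580649, 10967557 and 11560984 counts in the naive group and 13133653, 14621566 and 10490700 at 37 °C and 24 h. They were 16750082, 32668776 and 13423385 at 39 °C and 24 h, and 9279898, 15420580 and 10811090 at 37 °C and 48 h. Levels are given as normalised CPM, mean ± SD of n = 3 libraries, and positions as GRCm38 gene spans, which is the mm10 build.

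The 4 groups lay apart along the first principal component of 9248 genes with a mean of 10 CPM or more, which held 81.4% of the variance. Naive libraries lay between −91.0 and −85.6 on it, 37 °C 24 h libraries between −2.57 and 5.88, 39 °C 24 h libraries between 33.7 and 38.4, and 37 °C 48 h libraries between 50.3 and 54.6. Replicates within a group also differed along gene length. Genes shorter than 1 kb held 8.57% of the counts in naive replicate 1 against 6.23% and 6.36% in the other 2. They held 5.99% in 37 °C 24 h replicate 3 against 4.84% and 4.83%, and 7.003% in 39 °C 24 h replicate 1 against 4.81% and 5.63%. Transcripts of other cell types were present in every group. The summed level of 10 B cell markers was 728 ± 402 CPM in naive samples, 182 ± 119 at 37 °C and 24 h, 100.4 ± 65.7 at 39 °C and 24 h, and 39.1 ± 24.3 at 37 °C and 48 h. Myeloid markers summed to 240 ± 140, 55.5 ± 24.6, 33.1 ± 10.6 and 22.2 ± 0.343 CPM in the same order, and erythroid genes to 4909 ± 4160, 467 ± 671, 111 ± 126 and 9.87 ± 10.1 CPM. NK cell markers summed to 30.97 ± 17.9, 11.9 ± 4.05, 7.10 ± 2.84 and 3.41 ± 0.909 CPM, and CD4 and regulatory T cell markers to 97.3 ± 35.6, 71.7 ± 22.8, 56.3 ± 24.4 and 58.2 ± 17.8 CPM.

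**Figure D1:**
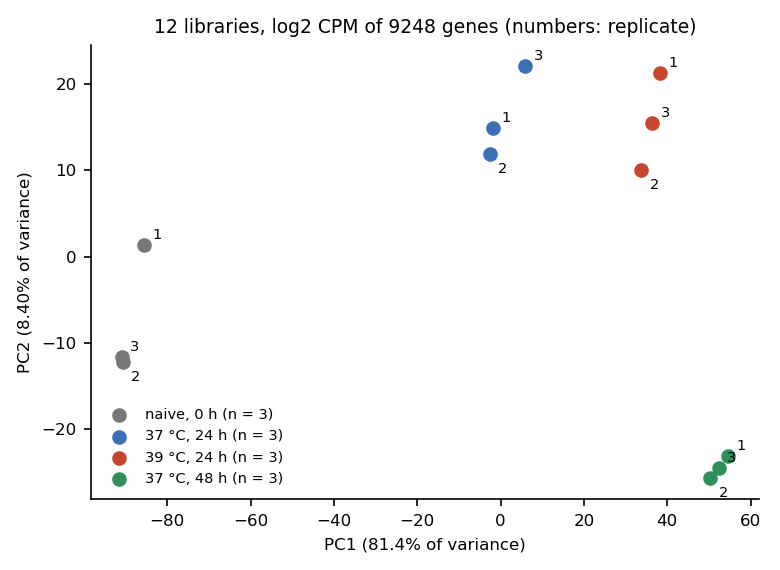
Principal components of log2 CPM over 9248 genes, with 1 point per library and the replicate number beside it. PC1 holds 81.4% of the variance and orders the groups from naive through 37 °C 24 h and 39 °C 24 h to 37 °C 48 h, and PC2 holds 8.40%.

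The series asks how a fever-range temperature changes CD8 T cell activation, which the comparison of 39 °C with 37 °C at 24 h addresses. At 39 °C the lists of chaperone, cell division, mitochondrial ribosome and effector genes were higher, and those of naive-state and interferon-stimulated genes were lower. These list calls hold at a preset correlation between genes, and none passed with an estimated correlation (adjusted p = 0.0588 to 0.481). Cirbp (ENSMUSG00000045193, chr10:80165985-80172786), an RNA-binding protein induced by cold, had 14.2 ± 2.21 CPM at 39 °C against 62.85 ± 6.35 at 37 °C, 4.397-fold lower (log2 fold change −2.14 ± 0.13 SE, adjusted p = 5.7e-06). Hsph1 (ENSMUSG00000029657, chr5:149614287-149636376), a heat-inducible chaperone of the HSP110 family, rose from 227.7 ± 6.86 to 533 ± 26.2 CPM, 2.34-fold (log2 fold change 1.23 ± 0.10 SE, adjusted p = 1.8e-05). By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 2268 of 14098 genes tested were higher and 2272 lower at 39 °C, 32.2% of all. Of these, 280 of the higher and 625 of the lower changed by at least 2-fold. The libraries of the 2 groups did not overlap for 46.2% of genes, against the 10% that chance gives for 3 against 3. The number of higher genes was 1326 without 37 °C 24 h replicate 1, 1320 without its replicate 2 and 1445 without 39 °C 24 h replicate 1, and the number of lower genes was 1491 without 37 °C 24 h replicate 2. Scaled by library size only, 1408 were higher and 2494 lower, 36.1% higher against 49.96% with the normalisation used.

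Protein-folding genes rose in several compartments. In the list of heat shock genes and cytosolic chaperones, 18 of 22 tested members rose and 0 fell (18 adjusted over the list alone, list test adjusted p = 3.1e-13, adjusted p = 0.0588 with an estimated correlation). Hspd1, the mitochondrial chaperonin HSP60, rose from 852 ± 63.0 to 1680 ± 55.8 CPM (1.97-fold, adjusted p = 3.8e-05). Dnajb1, an HSP40 co-chaperone, rose from 80.2 ± 3.58 to 112 ± 6.89 CPM (adjusted p = 0.00833, 0.0554 with library size only and 0.00102 to 0.0554 over 17 alternatives). Hspa1b, an inducible HSP70 gene, was low but rose from 0.412 ± 0.194 to 3.13 ± 0.410 CPM (adjusted p = 0.00609). This call ended with limma-voom (0.0797) and with the 3 libraries richest in short genes left out (0.0860, range 5.0e-06 to 0.0860). Its near-identical neighbour Hspa1a, with which it can share reads, had 0.563 ± 0.215 and 1.14 ± 0.176 CPM (adjusted p = 0.310). Of 18 genes of the endoplasmic reticulum (ER) unfolded protein response, 11 rose and 1 fell, Ddit3 (12 and 1 adjusted over the list alone, adjusted p = 1.1e-05, adjusted p = 0.160 with an estimated correlation). Among the higher were the ER chaperone Hsp90b1 (458 ± 21.5 to 890 ± 86.6 CPM) and the disulfide isomerase Pdia4 (1.54-fold). Members that went against their list, such as Ddit3 here, are outside the rule for named genes and were named after their values were seen. The amino acid response, targets of ATF4, had 13 of 25 genes higher and 0 lower (16 adjusted over the list alone, adjusted p = 2.2e-05, adjusted p = 0.250 with an estimated correlation). Psat1 of serine synthesis rose 1.52-fold and Mthfd2 of mitochondrial folate metabolism 1.55-fold. Rbm3 (ENSMUSG00000031167), another cold-inducible RNA-binding protein, fell from 514 ± 58.0 to 213 ± 40.2 CPM (log2 fold change −1.27 ± 0.13 SE, adjusted p = 5.7e-05). Its span overlaps an antisense gene and it has a pseudogene, so its counts are uncertain to that extent.

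Lists of mitochondrial protein synthesis genes were higher at 39 °C. Of 78 mitochondrial ribosomal protein genes, 34 rose and 0 fell (39 adjusted over the list alone, adjusted p = 3.9e-08, adjusted p = 0.481 with an estimated correlation), with a median log2 fold change of 0.43. The number that rose was 13, 11 and 52 without 37 °C 24 h replicates 1, 2 and 3, and 14 and 21 without 39 °C 24 h replicates 1 and 3. Mrpl45 (ENSMUSG00000018882, chr11:97315716-97329920) rose from 62.9 ± 5.19 to 98.9 ± 7.05 CPM (1.57-fold, adjusted p = 3.5e-04) and Mrpl1 by 1.72-fold. Of 33 mitochondrial translation factors and tRNA synthetases, 11 rose and 1 fell, Iars2 (12 and 1 adjusted over the list alone, adjusted p = 0.0251, adjusted p = 0.166 with an estimated correlation). Without 37 °C 24 h replicate 1, 6 rose, and 7 did without its replicate 2 or without 39 °C 24 h replicate 1 or 3. Gfm1, a mitochondrial elongation factor, rose from 88.1 ± 2.88 to 116 ± 5.05 CPM (1.32-fold, adjusted p = 0.00197). Tufm, mitochondrial elongation factor Tu, had 145 ± 23.6 and 188.5 ± 14.2 CPM (adjusted p = 0.0294). Its call ended without 37 °C 24 h replicates 1 (0.119) or 2 (0.123), without 39 °C 24 h replicates 2 (0.0593) or 3 (0.103), with library size only (0.0857) and with the compared groups alone (0.0628), over a range of 5.3e-04 to 0.123. The length trend moved with the mitochondrial ribosomal list, which holds short genes. Across genes the log2 fold change correlated with exonic length at Spearman rho = −0.246, and this list had a median length of 2513.5 bp against 3863 bp for all genes tested.

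Lists of respiratory and metabolic genes were also higher at the preset correlation, except the mitochondrially encoded mRNAs. Of 77 nuclear-encoded respiratory chain and ATP synthase genes, 7 rose and 1 fell, Cox7a2l (1 and 0 adjusted over the list alone, adjusted p = 4.6e-04, adjusted p = 0.667 with an estimated correlation). Over all genes tested 2268 of 14098 rose, a larger share than the 7 of 77 here. The mean log2 fold change of the respiratory list was 0.37, and 0.17 without 39 °C 24 h replicate 1 (adjusted p = 0.0229, the highest of 12 alternatives). The number that rose was 2, 1 and 18 without 37 °C 24 h replicates 1, 2 and 3, and 3 and 22 without 39 °C 24 h replicates 1 and 2. Cytochrome c, Cycs, was 2.19-fold higher (adjusted p = 0.00466). Of 12 mitochondrially encoded mRNAs, 3 rose, mt-Nd1, mt-Nd2 and mt-Nd4l, and 0 fell (2 adjusted over the list alone). The list did not pass (adjusted p = 0.0541). That list test passed without 37 °C 24 h replicate 2 (0.0154), without 39 °C 24 h replicates 2 (0.0202) or 3 (0.0224) and with library size only (0.0322, range 0.0154 to 0.885). mt-Nd2 lost its call (adjusted p = 0.00748) when length and GC trends were removed (0.123, range 1.5e-04 to 0.123). The complex IV subunit mt-Co1 had 4787 ± 404 CPM at 37 °C and 5600 ± 1715 at 39 °C (log2 fold change 0.23 ± 0.18 SE, adjusted p = 0.361), and its difference was −0.08 without 39 °C 24 h replicate 1. Reads of mitochondrial genes can also match nuclear copies of mitochondrial DNA, pseudogenes that held 0.859% to 1.69% of the counts of a library. Genes of the mitochondrial chromosome held 1.28% to 2.04%, so the pseudogene share is large beside theirs. Levels of mitochondrially encoded mRNAs are uncertain to that extent in every comparison. In the tricarboxylic acid (TCA) cycle list, 9 of 19 genes rose and 1 fell, Idh2 (11 and 1 adjusted over the list alone, adjusted p = 0.00846, adjusted p = 0.250 with an estimated correlation). Without 37 °C 24 h replicate 1 or 2, 4 rose, and 3 did without 39 °C 24 h replicate 1. Dlat of pyruvate dehydrogenase was 1.34-fold higher. Of 15 mitochondrial chaperones and proteases 6 rose and 0 fell (7 adjusted over the list alone, adjusted p = 0.0105, adjusted p = 0.250 with an estimated correlation), and 3 rose without 37 °C 24 h replicate 1 or 2. The mitochondrial HSP70 gene Hspa9 was 1.34-fold higher. Glycolysis had 13 of 21 genes higher and 1 lower, Pdk1 (13 and 1 adjusted over the list alone, adjusted p = 3.3e-04, adjusted p = 0.250 with an estimated correlation). Of these, 7 were higher without 37 °C 24 h replicate 1 or 2 and 8 without 39 °C 24 h replicate 3. It was led by the lactate exporter Slc16a3 (7.64 ± 1.72 to 21.9 ± 2.55 CPM, 2.90-fold) and Pgam1 (1.59-fold). Cholesterol synthesis had 6 of 22 higher and 0 lower (6 adjusted over the list alone, adjusted p = 0.00394, adjusted p = 0.250 with an estimated correlation). Idi1 was 1.72-fold and Cyp51 1.60-fold higher.

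Genes of the cytotoxic programme were higher at 39 °C and genes of the naive state lower. Of 20 effector molecules and cytokines, 10 rose and 2 fell, Tnfsf10 and Ccl5 (10 and 2 adjusted over the list alone, adjusted p = 9.4e-04, adjusted p = 0.462 with an estimated correlation). The mean log2 fold change of that list was 0.58, and 0.38 without 37 °C 24 h replicate 2. Perforin, Prf1, which forms pores in target cells, rose from 58.0 ± 1.92 to 105.5 ± 5.43 CPM (1.82-fold, adjusted p = 7.9e-05). Interferon gamma, Ifng, rose from 66.9 ± 40.7 to 258.5 ± 83.8 CPM (log2 fold change 1.96 ± 0.41 SE, adjusted p = 0.00391). Serpinb6b, a protease inhibitor with close paralogues, rose 3.57-fold. Granzyme B, Gzmb, had 1064 ± 256 and 1653 ± 153 CPM (adjusted p = 0.0279). That call ended without 37 °C 24 h replicates 1 (0.105) or 2 (0.116), without 39 °C 24 h replicates 1 (0.0641) or 3 (0.0921) and with library size only (0.0520), over a range of 0.00354 to 0.116. Tnf had 83.5 ± 8.41 and 113 ± 13.5 CPM (adjusted p = 0.0242). Its call ended without 37 °C 24 h replicates 1 (0.0686) or 2 (0.105), 39 °C 24 h replicates 1 (0.0762) or 3 (0.0996) and with library size only (0.0586), over a range of 0.00691 to 0.105. Il2 stayed low, with 3.47 ± 1.45 and 5.66 ± 2.85 CPM (adjusted p = 0.382). In the naive and quiescence list 16 of 22 genes fell and 0 rose (17 adjusted over the list alone, adjusted p = 8.6e-14, adjusted p = 0.147 with an estimated correlation). S1pr1 (ENSMUSG00000045092, chr3:115710433-115715072), the receptor by which T cells leave lymph nodes, had 26.3 ± 3.54 CPM against 138 ± 28.4, 5.23-fold lower (log2 fold change −2.39 ± 0.18 SE, adjusted p = 1.1e-05). Klf2, a quiescence transcription factor that drives S1pr1, was 4.65-fold lower. Activation receptors and transcription factors had 7 of 25 higher and 1 lower, Id2 (7 and 1 adjusted over the list alone, adjusted p = 0.128), and passed with length and GC trends removed and the replicate number as a block (0.0450). The transferrin receptor Tfrc rose from 286 ± 5.14 to 671 ± 113 CPM. Inhibitory receptors had 5 of 12 higher, Tigit, Pdcd1, Cd160, Havcr2 and Cd200, and 1 lower, Vsir (5 and 1 adjusted over the list alone, adjusted p = 0.0841). Tigit was 2.42-fold higher. That list passed without 39 °C 24 h replicate 2 (0.0176) and with library size only (0.0467). IL-2 and STAT5 targets had 2 of 13 higher, Lif and Ccnd3, and 5 lower, Socs3, Socs1, Bcl2, Il4ra and Osm (3 and 5 adjusted over the list alone, adjusted p = 0.264).

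Proliferation genes were higher at 39 °C. All 25 mitosis genes tested rose (25 adjusted over the list alone, adjusted p = 9.0e-39, adjusted p = 0.0588 with an estimated correlation). Cenpe, a kinetochore motor, rose from 30.5 ± 2.93 to 75.02 ± 3.21 CPM (2.46-fold, adjusted p = 1.4e-05) and the mitotic kinase Aurka 2.62-fold. Of 28 DNA replication genes 24 rose and 0 fell (26 adjusted over the list alone, adjusted p = 3.7e-14, adjusted p = 0.133 with an estimated correlation). The replication licensing factor Cdc6 rose 1.71-fold and the ribonucleotide reductase subunit Rrm1 1.74-fold. Ribosome biogenesis had 17 of 26 higher and 0 lower (23 adjusted over the list alone, adjusted p = 1.6e-05, adjusted p = 0.250 with an estimated correlation), including Wdr75 and Nop2. The number higher was 8 without 37 °C 24 h replicate 1 or 2 or 39 °C 24 h replicate 3, and 11 without 39 °C 24 h replicate 1. Of 82 cytosolic ribosomal proteins 1 rose and 0 fell (0 adjusted over the list alone, adjusted p = 0.121). That gene, Rps27l, is known as a p53 target (adjusted p = 0.0215). Its call ended without 37 °C 24 h replicates 1 (0.0837) or 2 (0.0880) or 39 °C 24 h replicate 1 (0.106), over a range of 3.9e-04 to 0.106. The cytosolic ribosomal list passed as higher without 37 °C 24 h replicate 3 (0.00143), without 39 °C 24 h replicate 2 (0.00170) and with library size only (0.0468). Of 19 p53 and DNA damage targets, 12 rose and 5 fell, Btg2, Trp53inp1, Xpc, Sesn1 and Rrm2b (13 and 5 adjusted over the list alone, adjusted p = 1.5e-04, adjusted p = 0.160 with an estimated correlation). Cdkn1a, the cell cycle inhibitor p21, rose from 9.33 ± 2.87 to 59.98 ± 13.6 CPM (log2 fold change 2.70 ± 0.29 SE, adjusted p = 7.2e-05). Phlda3 rose 4.89-fold and the death receptor Tnfrsf10b 2.46-fold. The largest increases by the rule for named genes were those of Serpine2, a secreted protease inhibitor (chr1:79794197-79861180, 2.19 ± 0.742 to 25.8 ± 4.35 CPM, 12.0-fold, adjusted p = 1.1e-05), and Tnfsf4, the ligand of OX40 (11.2-fold).

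Interferon-stimulated genes were lower at 39 °C. Of 27 tested, 19 fell and 1 rose, Bst2 (21 and 1 adjusted over the list alone, adjusted p = 1.2e-10, adjusted p = 0.250 with an estimated correlation). Irf7 (ENSMUSG00000025498), a transcription factor of the type I interferon response, had 6.56 ± 1.43 CPM against 32.0 ± 3.08, 4.77-fold lower (log2 fold change −2.25 ± 0.24 SE, adjusted p = 7.0e-05). Ifit3, which can share reads with its near-copy Ifit3b, was 4.96-fold lower. B cell and myeloid markers were lower in the same direction, and 24 of them summed to 237 ± 144 CPM at 37 °C and 133 ± 76.2 at 39 °C. The B cell list had 0 of 10 genes called (adjusted p = 0.264), the erythroid list 0 of 7 (0.264) and the NK list 0 of 6 (0.315). The myeloid list had 2 of 11 lower, Fcgr3 and Itgax (0.130), and the CD4 list 2 of 5 lower, Ikzf2 and Foxp3 (0.399). Without 37 °C 24 h replicate 2 the B cell, erythroid and myeloid lists passed as lower (0.0159, 0.0234 and 0.00565), and the myeloid list did without 39 °C 24 h replicate 3 (0.0210). With the replicate number as a block, B cell (0.00375) and myeloid (0.0152) markers passed as lower too. With length and GC trends removed beside the block, B cell (0.00262), myeloid (0.00846) and NK (0.0234) lists did. Hypoxia targets went both ways, with 5 of 15 higher, P4ha1, P4ha2, Ankrd37, Ero1l and Bnip3, and 5 lower, Pdk1, Kdm3a, Bnip3l, Ndrg1 and Mxi1 (8 and 5 adjusted over the list alone, adjusted p = 0.233). NRF2 targets had 4 of 16 higher, Prdx1, Gpx1, Txn1 and Gsr, and 1 lower, Gclc (5 and 1 adjusted over the list alone, adjusted p = 0.264). The call of Gsr (adjusted p = 0.0138) ended without 37 °C 24 h replicates 1 (0.0598) or 2 (0.0530), with library size only (0.152) and with no count filter (0.0789), over a range of 0.00343 to 0.152. In all, 17 of 29 lists passed. Each of them also passed under 12 alternatives that kept the preset correlation (highest adjusted p 0.0467), and 0 passed with an estimated correlation.

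**Figure D2:**
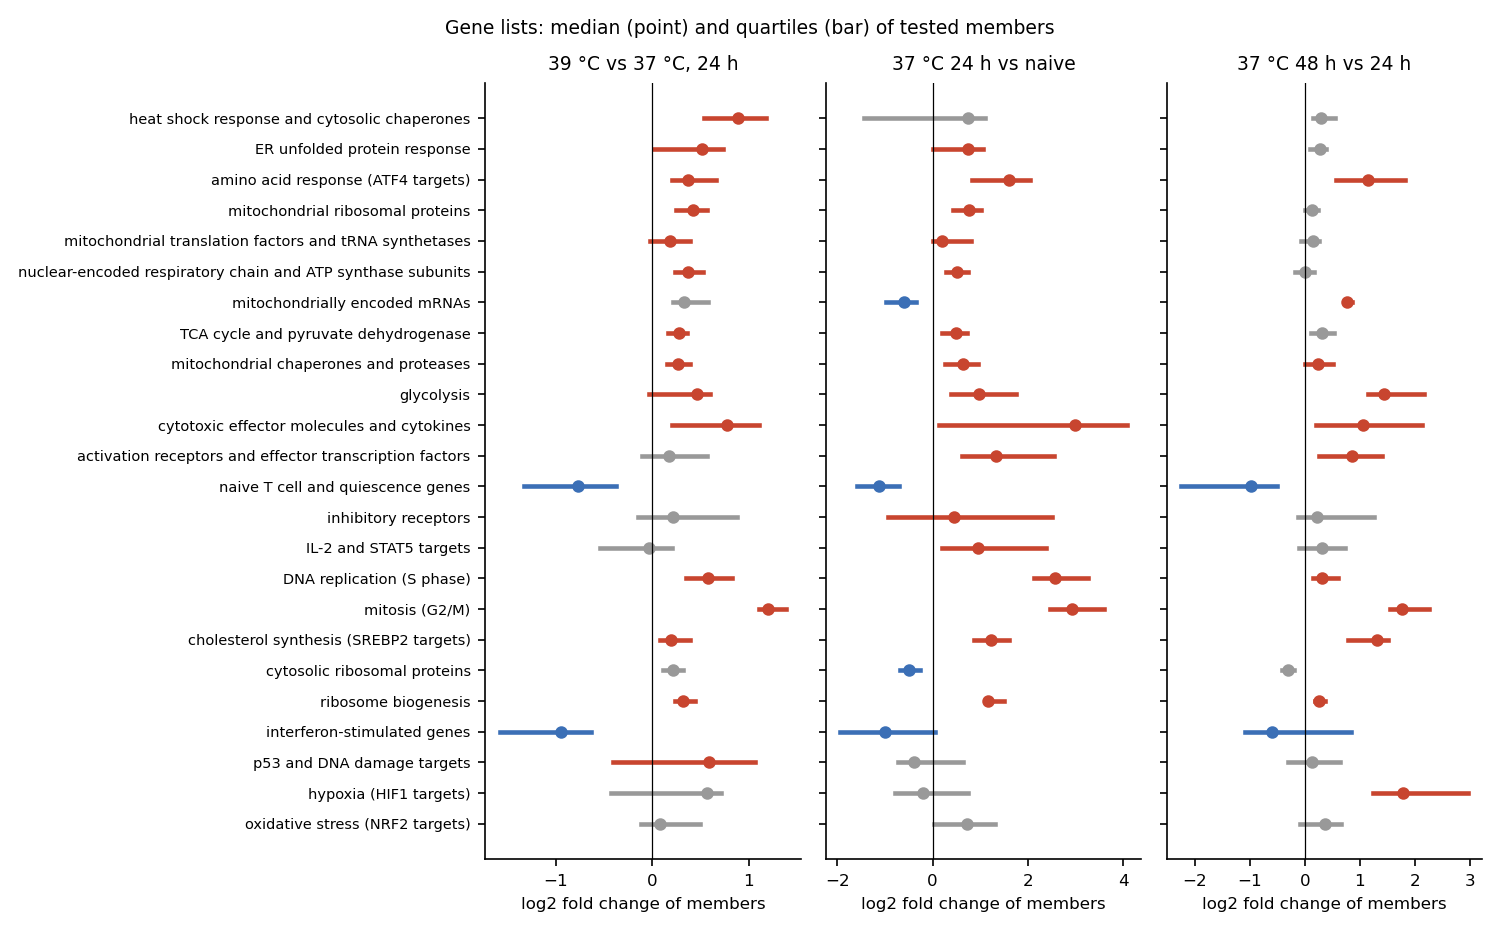
Median (point) and quartiles (bar) of the fitted log2 fold changes of the tested members of 24 gene lists in 3 comparisons. Red lists passed the list test as higher and blue lists as lower at a preset correlation, and grey lists did not pass. At 39 °C the mitochondrial ribosomal list has a median of 0.43 and the mitosis list of 1.20, and the interferon-stimulated list lies at −0.95.

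**Figure D3:**
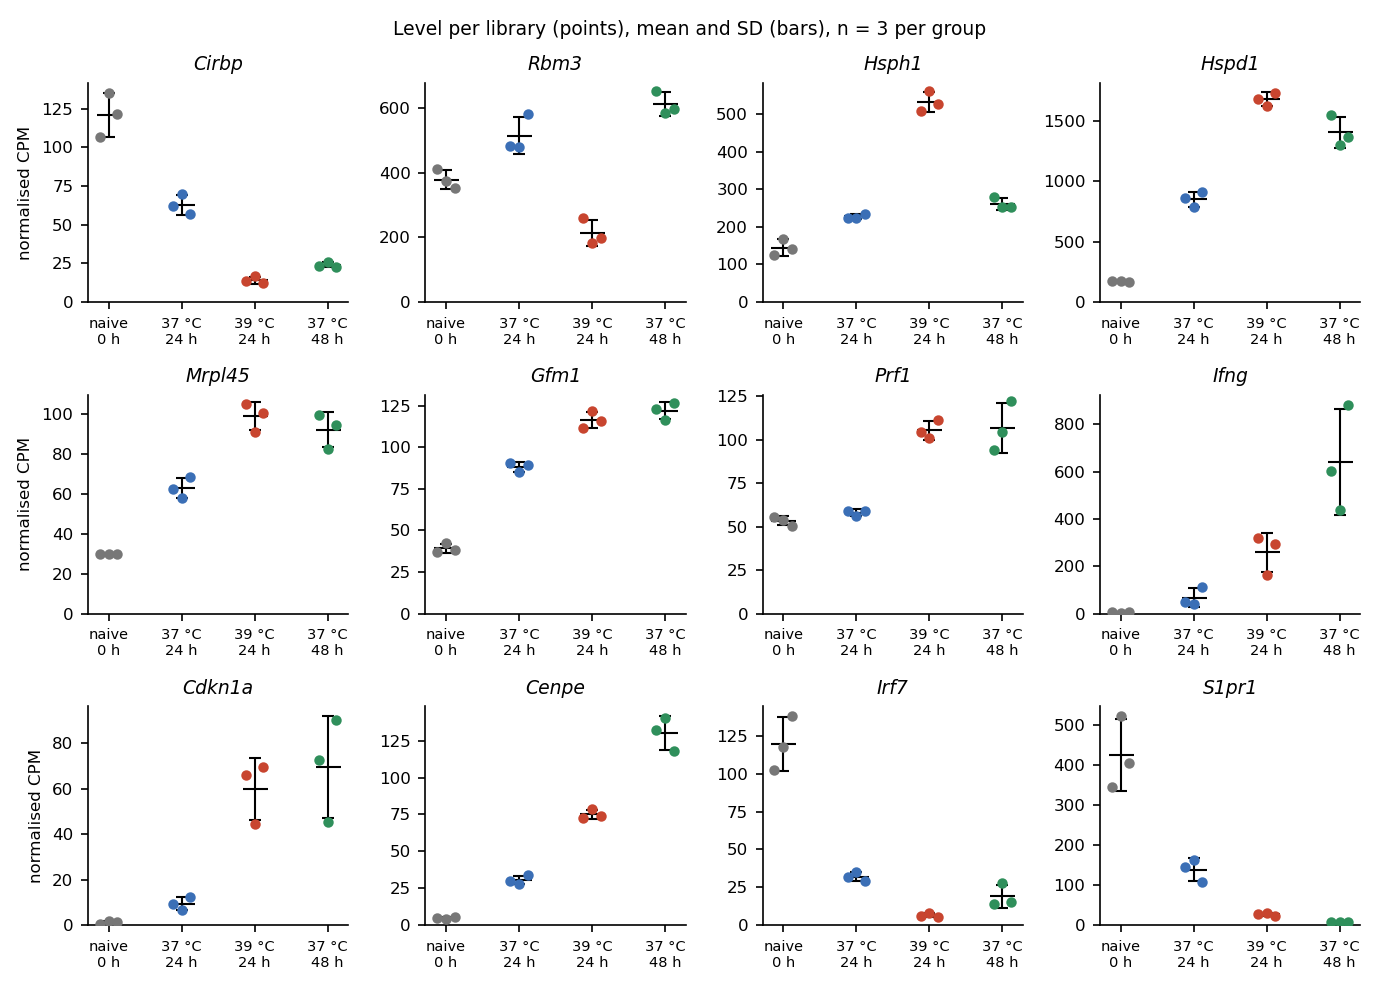
Normalised CPM of 12 genes in each library (points), with the mean and SD of each group (bars, n = 3) and every axis starting at 0. Cirbp and Rbm3 are lower and Hsph1, Hspd1, Mrpl45, Gfm1, Prf1, Ifng, Cdkn1a and Cenpe higher at 39 °C than at 37 °C after 24 h, with Irf7 at 6.56 against 32.0 CPM.

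Activation at 37 °C for 24 h, compared with naive cells, switched on division, growth and effector genes and lowered genes of the naive state. With an estimated correlation the division lists passed, and those of ribosome biogenesis (adjusted p = 0.0539), effector (0.325) and naive-state genes (0.185) did not. Gzmb rose from 6.32 ± 2.40 to 1064 ± 256 CPM (165-fold, adjusted p = 9.1e-10). Il2ra, the high-affinity IL-2 receptor chain, rose from 5.98 ± 2.63 to 374.5 ± 12.4 CPM (log2 fold change 5.99 ± 0.24 SE, adjusted p = 1.7e-09). Klf2 fell from 859 ± 126 to 156 ± 26.3 CPM, 5.49-fold, and Tcf7, a transcription factor of naive and memory T cells, 2.34-fold. Myc rose 2.50-fold, Mki67 5.85-fold and Ifng 13.5-fold. Of 14098 genes, 4242 were higher and 4078 lower, 59.0% of all, with 1897 and 1584 changed by at least 2-fold. Libraries did not overlap for 61.2% of genes against 10% by chance. With 0 counts in naive libraries, Spin4 was at least 73.7-fold higher and the chemokine Ccl1, whose span overlaps other genes, at least 69.9-fold higher, against a floor of 3 counts over the group. Crabp2, with 2 counts in the naive group, had a ratio of 87.1 (95% counting interval 23.9 to 724). The fitted log2 fold change of Ccl1 was 8.33 without 37 °C 24 h replicate 3 against 9.57 with it.

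All 28 DNA replication genes rose (28 adjusted over the list alone, adjusted p = 6.9e-53, adjusted p = 0.0202 with an estimated correlation). Cdc6 was 25.7-fold and the DNA methylation factor Uhrf1 19.9-fold higher. Of 25 mitosis genes 24 rose (24 adjusted over the list alone, adjusted p = 1.5e-32, adjusted p = 0.0448 with an estimated correlation). Top2a was 12.9-fold and Kif11 12.1-fold higher. Cholesterol synthesis had 20 of 22 higher (21 adjusted over the list alone, adjusted p = 2.4e-13, adjusted p = 0.0213 with an estimated correlation), led by Cyp51 and Idi1. All 26 ribosome biogenesis genes rose (26 adjusted over the list alone, adjusted p = 2.5e-17, adjusted p = 0.0539 with an estimated correlation), among them Dkc1 and Nolc1. Cytosolic ribosomal proteins went the other way, with 26 of 82 lower and Rps27l higher (9 and 1 adjusted over the list alone, adjusted p = 0.0101, adjusted p = 0.692 with an estimated correlation). Over all genes tested 4078 of 14098 were lower, a share near that of 26 in 82. Without naive replicate 1, the library richest in short genes, the cytosolic ribosomal list did not pass (0.174, mean log2 fold change −0.07 against −0.44). Then 4 of its genes were lower and 3 higher. Without 37 °C 24 h replicate 1 or 2, 7 of its genes were lower. The fall of Rps27, 2.72-fold with all libraries, had a log2 fold change of −0.81 against −1.45. Rps27l had 2.63 against 2.02 without that library. Of 78 mitochondrial ribosomal genes 61 rose and 0 fell (62 adjusted over the list alone, adjusted p = 1.2e-06, adjusted p = 0.627 with an estimated correlation). Mrpl45 was 2.11-fold and Mrpl19 1.84-fold higher. Mitochondrial translation factors had 16 of 33 higher and 2 lower, Ears2 and Vars2 (15 and 2 adjusted over the list alone, adjusted p = 0.0486, adjusted p = 0.173 with an estimated correlation). Gfm1 and the mRNA-stabilising factor Lrpprc were 2.24-fold and 2.03-fold higher. Respiratory chain genes had 37 of 77 higher and 1 lower, Cox7a2l (37 and 1 adjusted over the list alone, adjusted p = 0.0101, adjusted p = 0.692 with an estimated correlation). Without naive replicate 1, 63 were higher and the mean log2 fold change was 0.81 against 0.51. Mitochondrially encoded mRNAs had 8 of 12 lower and 0 higher (8 adjusted over the list alone, adjusted p = 0.0479, adjusted p = 0.627 with an estimated correlation), with a mean of −0.85 against −0.52 and 5 lower without naive replicate 1. The mRNA of cytochrome b, mt-Cytb, was 1.63-fold lower. TCA cycle genes had 14 of 19 higher (adjusted p = 0.0106, adjusted p = 0.325 with an estimated correlation), led by Fh1 and Idh3a. Mitochondrial chaperones and proteases had 11 of 15 higher and 1 lower, Spg7 (adjusted p = 0.00476, adjusted p = 0.185 with an estimated correlation), led by Hspa9 and Lonp1.

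Glycolysis had 17 of 21 genes higher and 2 lower, Pdk1 and Slc2a3 (adjusted p = 5.6e-07, adjusted p = 0.141 with an estimated correlation). Hexokinase 2, Hk2, rose 12.9-fold and Pgam1 4.27-fold. ATF4 targets had 20 of 25 higher and 1 lower, Ddit4 (21 and 2 adjusted over the list alone, adjusted p = 1.8e-09, adjusted p = 0.173 with an estimated correlation). Psat1 was 5.92-fold higher. ER unfolded protein response genes had 12 of 18 higher and 3 lower, Ddit3, Dnajc3 and Dnajb9 (12 and 3 adjusted over the list alone, adjusted p = 0.00483, adjusted p = 0.325 with an estimated correlation), with Sdf2l1 and Pdia3 among the higher. Effector molecules had 13 of 20 higher and 4 lower, Nkg7, Gzmm, Ccl5 and Gzma (14 and 4 adjusted over the list alone, adjusted p = 7.2e-06, adjusted p = 0.325 with an estimated correlation), including lymphotoxin alpha, Lta (9.99-fold). Activation receptors and factors had 19 of 25 higher and 3 lower, Cd69, Prdm1 and Id2 (adjusted p = 3.6e-11, adjusted p = 0.0250 with an estimated correlation). Tnfrsf9, the costimulatory receptor 4-1BB, was 23.8-fold higher. Naive and quiescence genes had 17 of 22 lower and 2 higher, Bach2 and Id3 (adjusted p = 1.3e-07, adjusted p = 0.185 with an estimated correlation). IL-2 and STAT5 targets had 8 of 13 higher and 1 lower, Socs3 (9 and 1 adjusted over the list alone, adjusted p = 1.1e-07, adjusted p = 0.0448 with an estimated correlation). The cytokine signalling inhibitor Cish was 18.8-fold higher. Inhibitory receptors had 6 of 12 higher and 4 lower, Cd244a, Tox, Vsir and Entpd1 (adjusted p = 0.0423, adjusted p = 0.325 with an estimated correlation). Pdcd1, which encodes PD-1, was 13.4-fold and Lag3 14.1-fold higher.

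Interferon-stimulated genes had 17 of 27 lower and 3 higher, Gbp2 and Gbp3 among them (adjusted p = 0.0136, adjusted p = 0.648 with an estimated correlation). Oasl1 was 8.16-fold lower. B cell markers had 10 of 10 lower (adjusted p = 0.0479, adjusted p = 0.648 with an estimated correlation), 5 without 37 °C 24 h replicate 1 or 2 and 4 without naive replicate 3. Myeloid markers had 9 of 11 (10 adjusted over the list alone, adjusted p = 0.0327, adjusted p = 0.627 with an estimated correlation) and erythroid genes 6 of 7 (7 adjusted over the list alone, adjusted p = 0.0327, adjusted p = 0.627 with an estimated correlation). Their sums fell beside the interferon-stimulated genes. By the rule for named genes, the largest decreases included those of Aqp1, Epb42 and Ace, with 0 counts at 37 °C and 24 h and at least 141-fold, 111-fold and 94.0-fold lower. Of these, Epb42 is a red cell membrane skeleton gene. DESeq2 did not call Ace (adjusted p = 0.0541, range 6.7e-08 to 0.0541). Another was Hspa1b, with 517 ± 305 CPM in naive samples against 0.412 ± 0.194 (adjusted p = 1.2e-08). The heat shock list went both ways, with 13 of 22 higher and 7 lower, a median log2 fold change of 0.75, a mean of −0.65 and a list test that pointed up without passing (adjusted p = 0.408). The p53 list had 7 of 19 higher and 10 lower (adjusted p = 0.404), with Gadd45a 8.08-fold lower. Hypoxia targets had 5 of 15 higher, Vegfa, Higd1a, Bnip3, Ero1l and Ndrg1, and 6 lower (adjusted p = 0.621). NRF2 targets had 8 of 16 higher and 3 lower, Osgin1, Hmox1 and Fth1 (9 and 3 adjusted over the list alone, adjusted p = 0.139). NK markers had 3 of 6 lower, Klra8, Ncr1 and Klri2 (6 adjusted over the list alone, adjusted p = 0.248). CD4 markers had 1 of 5 lower, Ikzf2 (adjusted p = 0.408). Of the 23 lists that passed, those of mitochondrially encoded mRNAs and B cell markers each ended without naive replicate 1 (0.107 and 0.0746) and, in turn, without naive replicate 2 (0.0656, mRNAs) or 3 (0.0732, B cells) and 37 °C 24 h replicates 1 (0.0727, mRNAs), 2 (0.0841, B cells) or 3 (0.0533, mRNAs). Translation factors and inhibitory receptors ended without naive replicate 1 (0.0571 and 0.0504), and TCA cycle, erythroid and myeloid genes did with length and GC trends removed (0.0538 each). The same correction ended B cell markers and translation factors (0.0861 each). The mean log2 fold changes before and after it were −4.52 and −4.68 for erythroid genes, −2.51 and −2.55 for myeloid and −2.23 and −2.31 for B cell markers, so these means did not shrink. They were 0.49 and 0.33 for TCA cycle genes and 0.32 and 0.23 for translation factors. The replicate block ended translation factors (0.0609) and mitochondrially encoded mRNAs (0.0659), as RLE scaling did (0.0547 and 0.0505), which also ended B cell markers (0.0547). Leaving out the 3 libraries richest in short genes ended both (0.0625 each), inhibitory receptors and myeloid markers (0.0560 each) and B cell markers (0.0649).

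The second day at 37 °C, 48 h against 24 h, brought higher glycolysis, hypoxia-target, sterol and effector genes and a further fall of naive-state genes. With an estimated correlation the glycolysis, hypoxia and sterol lists passed, and the effector (adjusted p = 0.535) and naive-state (0.0600) lists did not. Slc16a3 rose from 7.64 ± 1.72 to 256 ± 21.1 CPM, 33.9-fold (log2 fold change 5.08 ± 0.16 SE, adjusted p = 1.8e-09). Bnip3, a hypoxia-induced mitophagy receptor, rose from 5.93 ± 0.934 to 128 ± 5.81 CPM (21.4-fold, adjusted p = 4.1e-10). Gzmb rose 4.51-fold to 4798 ± 228 CPM, Ifng 9.64-fold, Il2ra 2.36-fold and Mki67 3.13-fold, while Klf2 fell 21.04-fold and Tcf7 2.77-fold. Myc had 467 ± 13.1 and 502.5 ± 20.9 CPM (adjusted p = 0.434). In total 3434 genes were higher and 3217 lower, 47.2% of those tested, with 963 and 1234 changed by at least 2-fold. Libraries did not overlap for 60.4% of genes against 10% by chance. Scaled by library size only, 2518 were higher and 3695 lower, 40.5% higher against 51.6%. Vldlr, a lipoprotein receptor, had 1 count at 24 h and a ratio of 379 (95% counting interval 67.6 to 15016). Its fitted log2 fold change was 10.12 without 37 °C 24 h replicate 1 against 8.22 with it. Cd7, a T cell surface protein, was 79.8-fold lower.

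All 21 glycolysis genes rose (21 adjusted over the list alone, adjusted p = 1.9e-29, adjusted p = 0.00424 with an estimated correlation). All 15 hypoxia targets rose (15 adjusted over the list alone, adjusted p = 6.7e-25, adjusted p = 9.3e-04 with an estimated correlation), and so did 25 of 25 mitosis genes (25 adjusted over the list alone, adjusted p = 1.0e-39, adjusted p = 0.0278 with an estimated correlation). The glucose transporter Slc2a3 rose 6.94-fold, the ER oxidoreductase Ero1l 5.90-fold and cyclin B1, Ccnb1, 7.79-fold. Cholesterol synthesis had 19 of 22 higher and 0 lower (19 adjusted over the list alone, adjusted p = 6.9e-24, adjusted p = 0.00424 with an estimated correlation). Idi1 was 4.16-fold higher. ATF4 targets had 24 of 25 higher (adjusted p = 1.6e-17, adjusted p = 0.0600 with an estimated correlation). Asparagine synthetase, Asns, was 9.11-fold higher. Naive and quiescence genes had 17 of 22 lower and 0 higher (adjusted p = 7.4e-17, adjusted p = 0.0600 with an estimated correlation). Effector genes had 13 of 20 higher and 0 lower (14 and 1 adjusted over the list alone, adjusted p = 7.5e-04, adjusted p = 0.535 with an estimated correlation). Activation receptors and factors had 15 of 25 higher and 2 lower, Id2 and Egr1 (16 and 2 adjusted over the list alone, adjusted p = 4.7e-05, adjusted p = 0.0799 with an estimated correlation). DNA replication had 14 of 28 higher (adjusted p = 7.5e-04, adjusted p = 0.535 with an estimated correlation). Ribosome biogenesis had 16 of 26 higher (adjusted p = 0.0245, adjusted p = 0.565 with an estimated correlation), such as nucleolin, Ncl (1.49-fold). The number higher was 9 and 5 without 37 °C 24 h replicates 1 and 2, and 5 and 10 without 37 °C 48 h replicates 1 and 3.

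Among mitochondrial lists, the mitochondrially encoded mRNAs had 9 of 12 higher (9 adjusted over the list alone, adjusted p = 0.00711, adjusted p = 0.535 with an estimated correlation). The respiratory complex I gene mt-Nd4 was 1.77-fold higher. With length and GC trends removed neither the list (0.554, mean log2 fold change 0.39 against 0.90) nor mt-Nd4 (0.287) passed. Mitochondrial chaperones and proteases had 7 of 15 higher and 0 lower (adjusted p = 0.0322, adjusted p = 0.502 with an estimated correlation), a call that ended with library size only (0.0696). Lonp1 was 1.85-fold higher. Mitochondrial ribosomal genes had 7 of 78 higher and 2 lower, Mrpl24 and Mrpl58 (2 and 1 adjusted over the list alone, adjusted p = 0.281). They passed as higher without 37 °C 24 h replicate 3 (0.0302) and with the 3 libraries richest in short genes left out (0.0294). With these left out, ER (0.0438), heat shock (0.0438), IL-2 and STAT5 (0.0342) and TCA cycle (0.0455) lists passed and the myeloid list ended (0.163). Translation factors had 8 of 33 higher and 3 lower, Pars2, Fars2 and Vars2 (8 and 2 adjusted over the list alone, adjusted p = 0.292). TCA cycle genes had 10 of 19 higher and 2 lower, Idh2 and Idh3g (adjusted p = 0.0627). Respiratory chain genes had 5 of 77 higher, Atp5f1, Atp5b, Atp5a1, Cycs and Uqcrfs1, and 2 lower, Cox7a2l and Atp5e (0 and 1 adjusted over the list alone, adjusted p = 0.965). The respiratory list had a median log2 fold change of 0.01, a mean of −0.01 and a list test that pointed up. Cytosolic ribosomal proteins had 2 of 82 lower, Rplp2 among them (0 adjusted over the list alone, adjusted p = 0.0627). That list passed as lower without 37 °C 24 h replicates 1 (0.0193) or 2 (0.0103) or 37 °C 48 h replicate 1 (0.0365), with library size only (0.0244) and with the replicate block (0.0440). The call of Rplp2 (adjusted p = 0.0250) ended without 37 °C 24 h replicate 3 (0.0823) or 37 °C 48 h replicates 1 (0.0847) or 2 (0.0883) and with length and GC trends removed (0.0631), over a range of 0.00509 to 0.0883. Heat shock genes had 9 of 22 higher and 1 lower, Dedd2 (adjusted p = 0.0779), and passed without 37 °C 48 h replicate 3 (0.04995). ER unfolded protein response genes had 10 of 18 higher (10 and 1 adjusted over the list alone, adjusted p = 0.0779). IL-2 and STAT5 targets had 8 of 13 higher and 2 lower, Socs3 and Socs1 (adjusted p = 0.0779). Both lists passed without 37 °C 24 h replicate 3 (0.0441 and 0.0298) and with length and GC trends removed (0.0434 and 0.0203), as TCA cycle genes (0.0491) and B cell markers (0.0453) then did. Interferon-stimulated genes had 13 of 27 lower and 7 higher (8 higher and 13 lower adjusted over the list alone, adjusted p = 0.0212, adjusted p = 0.608 with an estimated correlation). Ifit3 was 9.18-fold lower, with a log2 fold change of −3.20, and −3.85 without 37 °C 48 h replicate 2. The interferon-stimulated list ended without 37 °C 48 h replicates 1 (0.0555) or 3 (0.0506). Its mean log2 fold change was −0.34, and −0.21, −0.76 and −0.16 without 37 °C 48 h replicates 1, 2 and 3. Myeloid markers had 6 of 11 lower (7 adjusted over the list alone, adjusted p = 0.0375, adjusted p = 0.608 with an estimated correlation), a call that ended without 37 °C 24 h replicates 1 (0.0608) or 3 (0.0961) and 37 °C 48 h replicate 2 (0.0757), with 3 genes lower without either of the last 2. B cell markers had 4 of 10 lower, Cd79b, Cd79a, Bank1 and Blk (adjusted p = 0.0641), and passed without 37 °C 24 h replicate 2 (0.00393) and without 37 °C 48 h replicate 3 (0.0236). Erythroid genes had 4 of 7 lower, the haemoglobin genes Hba-a1, Hba-a2, Hbb-bs and Hbb-bt, which share reads (5 adjusted over the list alone, adjusted p = 0.104). The list passed without 37 °C 24 h replicate 2 (0.0147), and without 37 °C 24 h replicate 3 all 4 genes lost their call (0.0589, 0.113, 0.0601 and 0.132), as they did with limma-voom (0.187, 0.239, 0.109 and 0.274). Their log2 fold changes were −3.47, −2.94, −3.05 and −2.89 without that library, against −5.93, −5.30, −5.77 and −5.32 with it. They were −7.56, −6.57, −7.15 and −5.95 without 37 °C 48 h replicate 3. Without 37 °C 48 h replicate 1 the call of Hba-a2 ended (0.0503), and without replicate 2 those of Hba-a2 (0.0572) and Hbb-bt (0.0611), while Hba-a1 had −5.27. NK markers had 4 of 6 lower, Ncr1, Klrb1c, Klra4 and Klra8 (adjusted p = 0.148). With the replicate number as a block, B cell (3.7e-07), erythroid (0.00705), NK (0.0344) and IL-2 and STAT5 (0.0440) lists passed, and each did with length and GC trends removed beside it (1.7e-07, 0.00752, 0.0143 and 0.00561). CD4 markers had 1 of 5 higher, Ikzf2, and 1 lower, Foxp3 (adjusted p = 0.881). Inhibitory receptors had 5 of 12 higher, Ctla4, Havcr2, Lag3, Cd200 and Tigit, and 1 lower, Vsir (adjusted p = 0.136). p53 targets had 7 of 19 higher and 5 lower, Sesn1, Xpc, Trp53inp1, Btg2 and Bbc3 (adjusted p = 0.396). NRF2 targets had 8 of 16 higher and 1 lower, Fth1 (adjusted p = 0.215).

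Across the whole 48 h at 37 °C, 5317 genes were higher and 5215 lower than in naive cells, 74.7% of those tested, with 3081 and 3135 changed by at least 2-fold. Libraries of the 2 groups did not overlap for 76.8% of genes, against 10% by chance.

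Genes that differed with temperature at 24 h were largely those that differed between 24 h and 48 h at 37 °C. Of the genes called in both comparisons, 1535 were higher in both and 1718 lower in both, where independent lists would share 552 and 518. Another 27 and 51 went in opposite directions, where independent lists would share 518 and 553. Slc16a3, Gzmb, Ifng, Cenpe and Tfrc rose in both comparisons and Klf2 fell in both. Rbm3 did not follow, with 514 ± 58.0 CPM at 37 °C and 24 h, 611 ± 36.8 at 48 h and 213 ± 40.2 at 39 °C. Across 14098 genes, which are not independent replicates, the log2 fold changes correlated at Pearson r = 0.705 and Spearman rho = 0.680, with the same sign for 75.5% of genes. Both comparisons use the same 37 °C 24 h libraries, and with no effect simulated this gave a median r of 0.507 and 66.9% of equal signs over 50 draws. Redrawn replicate deviations gave a median r of 0.542 with a 95th percentile of 0.877, and a 95th percentile of 84.9% for equal signs, so r and the share of equal signs lay within what sharing libraries can give. The covariance was 0.416 against a simulated median of 0.0422 and maximum of 0.0485, a difference of 0.373, and against a 95th percentile of 0.0834 for redrawn deviations. Against the change from naive to 48 h, which shares no library with the temperature comparison, r was 0.671. Simulated groups with no effect had 0 genes called in the same direction in both comparisons. The simulation leaves out the effects and independent lists leave out the sharing. The 3 libraries of the 37 °C 24 h group cannot be split into 2 sets of at least 2, so part of the overlap of calls may come from sharing them.

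**Figure D4:**
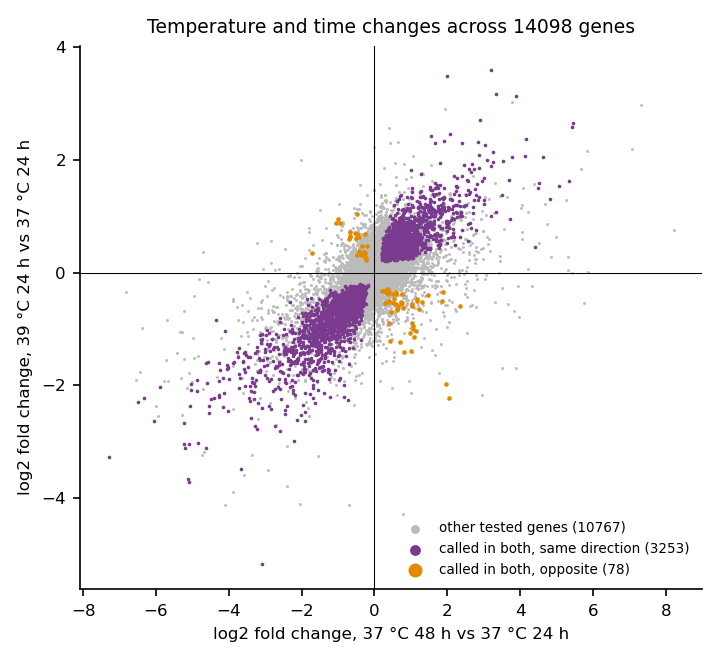
Log2 fold change at 39 °C against 37 °C, both at 24 h (vertical axis), and at 48 h against 24 h, both at 37 °C (horizontal axis), for 14098 genes, 1 point each. Purple points are the 3253 genes called in both comparisons in the same direction, orange points the 78 called in opposite directions and grey points the other 10767.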

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

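Removal of length and GC trends, leaving out 3 libraries together and thinning were tests chosen after the results were seen, and the others were chosen before. Of 4540 genes called between 39 °C and 37 °C at 24 h, 98.3% kept their call with RLE size factors, 96.3% with DESeq2, 98.6% with limma-voom, 99.8% with the replicate block, 88.5% with length and GC trends removed, 88.1% with 3 libraries left out, 83.2% with the compared groups alone, 82.6% with no count filter, 80.7% with library size only and 78.0% after thinning to the lowest total. Without 1 library the share was 62.7%, 60.8% and 87.6% for 37 °C 24 h replicates 1, 2 and 3, and 68.5%, 86.2% and 70.1% for those at 39 °C. Of the calls shared in these fits, 0 turned direction. Fewer counts thus cost calls: thinned libraries gave 1733 higher and 2019 lower. With library size only, 1408 genes were higher in place of 2268, and the median log2 fold change of all genes was −0.084 in place of 0.0168. For 48 h against 24 h that median was −0.097 in place of 0.0092. Leaving out 1 library gave 1320 to 2208 higher genes (lowest without 37 °C 24 h replicate 2, highest without 39 °C 24 h replicate 2) and 1491 to 2614 lower genes (lowest without 37 °C 24 h replicate 2, highest without its replicate 3). Without 37 °C 24 h replicate 1 there were 1326 higher genes and without 39 °C 24 h replicate 1 there were 1445. Fewer libraries lower the power of the test, and the cause of the differences between libraries was not tested. The counts of genes in the other 3 comparisons stayed within 1.5 times under every alternative run. The list tests rest most on 1 choice. With an estimated correlation 0 of 17 lists passed for 39 °C against 37 °C, 5 of 23 for 24 h against naive and 4 of 14 for 48 h against 24 h. After length and GC trends were removed, with an estimated correlation, 0, 4 and 7 passed. Members of a list vary together between libraries, which that correlation counts against the list by its construction. With the replicate block, 2694 genes were higher and 2752 lower at 39 °C, and 19, 21 and 19 lists passed. Same-number replicates correlated at −0.22, 0.73 and 0.50 in that comparison, at −0.35, 0.53 and −0.15 for 24 h against naive and at −0.13, 0.65 and 0.43 for 48 h against 24 h. For 48 h against naive, where each pair correlated, the block gave 5466 higher and 5356 lower genes. Lists whose calls the block changed, alone or with length and GC trends removed, are named in the report. Among named genes the block gave Il2 a call at 39 °C (adjusted p = 0.0453, range 0.0453 to 0.741). With those trends removed beside it, Myc passed as higher at 48 h (0.0386, range 0.0386 to 0.992). The correlation of the 2 effects across genes was 0.705, was 0.671 against 48 h minus naive, 0.748 over genes with a mean of 10 CPM or more, and 0.700 to 0.719 with each of the 3 shared 37 °C 24 h libraries left out in turn. Libraries of the other groups were not left out for this value. Among named genes, the values that turned direction belong to genes that did not pass with the normalisation used: Myc at 48 h against 24 h had a log2 fold change of −0.0022 with library size only. mt-Co1 at 39 °C had −0.0427 with length and GC trends removed, −0.0433 with the replicate block added to that, −0.142 with 3 libraries left out and −0.0806 without 39 °C 24 h replicate 1, within −0.0806 to 0.357 over libraries left out. Over all genes, some genes called in both fits turned direction when length and GC trends were removed. These were 45 of 9507 shared calls for 48 h against naive and 4 of 5594 for 48 h against 24 h. With the block added they were 53 of 9611, 4 of 5786 and, for 24 h against naive, 1 of 7744. The cause of these turns was not tested. Over all alternatives, 2830 values of named genes kept direction and side of the threshold, 52 lost the call, 2 gained it and 5 turned direction. Of the list results 1046 kept their side of the threshold, 123 lost the call, 49 gained it and 0 passed in the opposite direction. A list that turned direction without passing was counted by its side of the threshold alone, unlike a named gene. At 39 °C, for example, the mean log2 fold change over 12 alternatives ran from −0.198 to 0.0108 for IL-2 and STAT5 targets. It ran from −3.18 to 0.167 for erythroid genes.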

Other observations

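Of the tests here, the splits of libraries and the matched lists were chosen before the results were seen, and the others after. The 6 libraries of a comparison can be split into 3 and 3 in 10 ways, so the share of splits with a result as large is never under 1 in 10. The splits therefore cannot reach 0.05. The real split called 4540 genes for 39 °C against 37 °C and the highest other 6. It called 8320 against 0 for 24 h against naive, 6651 against 0 for 48 h against 24 h and 10532 against 0 for 48 h against naive. In each comparison 1 of the 10 splits, the real one, gave as many calls.

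Mitochondrial ribosomal protein genes were higher at 39 °C, and the libraries also differed along gene length, with these genes among the shorter. With length and GC trends removed per library, the mean log2 fold change of the list was 0.385, 41 genes were called higher and 0 lower, and the list test passed (adjusted p = 1.6e-08), which argues against these trends as the whole cause. The list median lay at percentile 100 of 10000 random lists matched on length, GC content and level, 0.43 against a highest random median of 0.34. Random matched lists had a median of 0.17, so part of the rise may be shared by other short genes. Correlated members are not modelled by random lists, and with an estimated correlation the list did not pass. Within these limits, a rise of the list with temperature is a hypothesis.

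Interferon-stimulated genes were lower at 39 °C, beside lower sums of B cell and myeloid markers, cells that can make or respond to interferon and that negative selection should remove. Within groups, over 12 libraries, the list mean changed by −0.0675 log2 units per log2 unit of the marker sum, and by −0.146 to 0.0132 with 1 library left out, where a slope of 1.17 would account for the difference. That argues against fewer carried-over cells as the direct source of these transcripts. With length and GC trends removed the mean log2 fold change was −1.11 (20 lower and 1 higher) and the list test still passed, which argues against those trends. An effect of temperature on interferon signalling and a change in how such cells act on the T cells both stay open.

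Changes at 39 °C and changes from 24 h to 48 h went together across genes. The covariance was 0.416, against a highest value of 0.0485 in simulated unchanged groups and a 95th percentile of 0.0834 in redrawn replicate deviations, which argues against the shared 37 °C 24 h libraries as the whole cause. A candidate explanation is that activation runs the same course faster at 39 °C. If 39 °C levels only lay between those of 24 h and 48 h at 37 °C, genes beyond both would be due to chance alone. There were 655, 342 above and 313 below, and 824 with length and GC trends removed. Both comparisons use the same 39 °C libraries, whose deviations can carry genes beyond both 37 °C groups at once. With 39 °C means held between those of the 37 °C groups, redrawn replicate deviations gave a median of 5.5 over 50 draws. Their 95th percentile was 82.15 and their highest count 469, and simulated negative binomial counts gave at most 37. Without 39 °C replicate 1, 2 or 3 the observed count was 311, 800 or 319. Each of these lay above the 95th percentile, and 311 and 319 lay below the highest draw. These fits hold fewer libraries than the draws, which lowers their counts of calls, so the 2 are not like for like. The rule for this test asked for more than the highest draw with any 39 °C library left out. By that rule the count does not decide, and a faster course stays open. A gene that peaks between 24 h and 48 h would lie beyond both as well.

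The 39 °C 24 h libraries were also set against 37 °C 48 h, where temperature and time differ together, after the other results were seen. There, 1764 genes were higher and 2222 lower at 39 °C and 24 h. Of 4540 genes called between 39 °C and 37 °C at 24 h, 53.5% had a 39 °C mean between those of the 37 °C groups. Among genes called in the same direction in both comparisons, the change at 39 °C was 0.754 of the second-day change in log2 units (median, quartiles 0.570 and 1.01). That choice of genes keeps only positive ratios and leaves out small changes at 39 °C, which can raise the median. Over all genes tested the slope of the change at 39 °C on the second-day change was 0.437, and both values share the 37 °C 24 h libraries. Lists of heat shock (adjusted p = 9.8e-06), mitochondrial ribosomal (1.9e-04), respiratory chain (8.3e-04), DNA replication (0.0226) and p53 (0.0153) genes passed as higher, and interferon-stimulated genes as lower (0.0153), at 39 °C than in either 37 °C group. The members called against both were 10 of 22 heat shock, 9 of 78 mitochondrial ribosomal, 0 of 77 respiratory chain, 6 of 28 DNA replication and 8 of 19 p53 genes above both, 1 p53 gene below both, and 6 of 27 interferon-stimulated genes below both. None of these 6 passed against 48 h with an estimated correlation (0.126 to 0.705). Glycolysis (21 of 21 genes), hypoxia (13 of 15) and cholesterol synthesis (19 of 22) were lower at 39 °C and 24 h than at 48 h, also with an estimated correlation (0.00120, 7.8e-05 and 0.00120). Genes beyond both 37 °C groups, named after their values were seen, included the p53 target Phlda3 (26.6 CPM against 5.52 and 7.39), the chaperonin partner Hspe1 (726 against 286 and 326) and the chemokine Xcl1 (1154 against 539 and 498) above, and Irf7 (6.56 against 32.0 and 19.0) and Tent5a (7.43 against 19.9 and 35.3) below.

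Naive samples held 517 ± 305 CPM of the inducible HSP70 gene Hspa1b, against 0.412 ± 0.194 at 37 °C and 24 h and 3.13 ± 0.410 at 39 °C and 24 h. The handling of cells before lysis is not described closely enough in the labels to say what naive samples met before lysis.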
